A study of Drosophila melanogaster with 10 samples.

How the data were processed

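RNA sequencing libraries were made from adult male Drosophila melanogaster midguts. Both groups carried the Dredd D44 mutation. Dredd is the caspase that the IMD pathway, an innate immune pathway of flies, uses to activate its transcription factor Relish. The control group carried the mex-GAL4 driver over a wild-type chromosome, and the other group carried mex-GAL4 over UAS-PGRP-LE. The mex driver is active in enterocytes, the absorptive cells of the gut, and GAL4 switches on the UAS transgene there. PGRP-LE is a receptor for bacterial peptidoglycan. Each group had 5 libraries, which the series describes as biological replicates per genotype, and RNA was taken from 20 midguts. Flies were kept on yeast alone until 7 days after eclosion at 25 °C with 12 h of light. Libraries were stranded and made from polyA RNA, per the labels' protocols.

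The deposited expression table holds TPM (transcript abundance scaled to a fixed total) for 31181 rows, 92 of them ERCC spike-in sequences added as external standards, and each column sums to that total. The submitters' processing notes name FastQC, Trim Galore, kallisto and edgeR, with genome build BDGP6, without versions or settings. The strand setting used for the quantification is not given in the sources used here. TPM values keep no record of sequencing depth, so the depth of each library is unknown and no counting interval is given. A second table holds the authors' own comparison, with a log2 fold change and a p-value per gene for 10682 genes, both made by the authors. RUVSeq, a correction for unwanted variation, is named in that table's title without its factors. The p-value column deposited by the authors looks unadjusted, since 108 of 114 values with a tied p also had a tied fold change.

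Transcript rows were matched to genes with the Ensembl release 115 annotation of BDGP6.54, from which all coordinates come, and 31048 of 31089 matched. The other 41 rows held 0.0354% ± 0.00288 of the TPM in controls and 0.0424% ± 0.00114 in overexpression libraries (SD, n = 5). Summing gave 14292 genes, and 79 tested genes had values identical to another gene's, for a reason that was not examined. Genes with at least 1 TPM in at least 5 of the 10 libraries were tested, 8722 in all. Values were compared as log2(TPM + 1), a scale that understates the change of genes of low level. The test was limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend and robust), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 changes are overexpression minus control, with the standard error (SE) from limma. "Rose" and "fell" are used for genes past that threshold.

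A total of 38 gene lists were fixed, including markers of other cell types that the dissection could hold. The 35 lists with 3 or more tested members were compared with the other genes by limma's camera with a preset correlation of 0.01, and again with an estimated correlation. Single values per library were compared by exact permutation tests of 5 against 5 in SciPy 1.17.1, two-sided, whose smallest possible p is 0.00794, and adjusted over 42 such values.

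The genes named were set by a rule. It took PGRP-LE, Dredd and w, and the 10 largest changes each way among genes whose groups did not overlap. It also took the 4 members with the smallest p of the antimicrobial peptide, IMD component, IMD regulator and autophagy lists. From each other list past its test or with at least 3 members past the threshold it took 3, and from each list of another cell type 1. The rule gave 124 distinct genes. Genes named outside it were chosen after their values were seen. The lists, the tests, the rule and most alternatives were made before the data were examined.

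Alternatives covered other pseudocounts (0.1 and 5), other filters, median-of-ratios rescaling, quantile normalization, limma without trend and robust, array weights, a replicate block and 1 or 2 factors of unwanted variation. Each library was also left out in turn, and stricter thresholds were applied. The 100 regroupings of the samples were drawn from 126 possible splits. Rescaling to the spike-ins, a total without spike-ins and unmatched rows, omission of replicate 2 from both groups, and a pseudocount of 5 for the lists were added after seeing the data.

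The gene-wise test was checked on simulated data for this comparison, over 8722 genes of which 200 were changed. It recovered 32% of genes changed by 0.25 on the log2 scale, 90% at 0.5, and 100% at 1 and at 2. False calls made up 6.94% of calls, and 0 genes were called when nothing was changed. The simulated genes varied independently and few were changed, whereas 5490 genes passed the threshold in the data, so these rates may not hold there.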

Results

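The data set compared the midgut transcriptomes of Dredd mutant males with and without overexpression of PGRP-LE in enterocytes, with 5 libraries per genotype. The comparison addresses what the receptor does to gut gene expression when the caspase that normally relays IMD signalling is mutated. The number of genes at 1 TPM or more was 8598 ± 20.5 in controls and 8709 ± 38.3 with overexpression (SD, n = 5). The 20 most abundant genes held 21.6% ± 0.728 of TPM in controls and 18.7% ± 0.323 with overexpression (SD, n = 5; exact permutation test, p = 0.00794, the smallest that 5 against 5 allows). Spike-ins held 1.299% ± 0.0432 and 1.32% ± 0.147 of TPM (SD, n = 5; exact permutation test, p = 0.738). The first principal component held 71% of the variance and separated the genotypes.

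PGRP-LE, the gene driven by the transgene, stood at 38.2 ± 2.33 TPM in controls and 4534 ± 295 TPM with overexpression (SD, n = 5), a log2 change of 6.85 ± 0.06 (SE; limma adjusted p = 1.58e-15). Transcripts of the endogenous gene (FBgn0030695, chromosome X, 15801153 to 15803880, minus strand) and of the transgene share sequence and were not separated. Dredd, mutated in both groups (FBgn0020381, chromosome X, 633622 to 635545), was still represented by transcripts. It rose from 23.2 ± 2.01 to 33.0 ± 2.15 TPM, a log2 change of 0.49 ± 0.06 (limma adjusted p = 3.43e-05). The white gene w, which is commonly carried as a marker on transgenes, rose from 3.06 ± 0.224 to 17.4 ± 3.15 TPM.

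Of the 8722 genes tested, 3499 were higher and 1991 lower with PGRP-LE overexpression. Changes of at least 1 on the log2 scale numbered 336 upward and 297 downward. The groups did not overlap for 4214 genes, where chance gives 0.794% of genes. The share of calls that were higher, 63.7%, depended on scaling. Median-of-ratios rescaling gave 2753 higher and 2717 lower (50.3% higher), and quantile normalization 2986 and 2566 (53.8% higher). Both methods bring the median change near 0 (-0.003 and 0.02), so they cannot tell whether the upward excess is real. Rescaling to the spike-ins, added after seeing the data, gave 2582 higher and 1649 lower (61.0% higher). The median change of all genes was 0.09 on the log2 scale in the TPM as deposited.

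Among the largest rises, CG5883 (FBgn0036225, 3L, 11943640 to 11944852) went from 0.281 ± 0.138 to 190 ± 25.5 TPM, a log2 change of 7.22 ± 0.10. CG7298 rose from 8.28 ± 7.41 to 725 ± 94.1 TPM and CG11893 from 13.9 ± 8.24 to 985 ± 129 TPM. CG33468, CG14810 and Mov10, which encodes an RNA helicase, rose by 5.79, 5.51 and 5.25 on the log2 scale. CG30025, a trypsin-like gene, rose from 6.62 ± 2.02 to 476 ± 81.4 TPM, but has near-identical neighbouring copies, so its own level is uncertain. The glutathione S-transferase genes GstD4 and GstD2 completed the 10 largest rises.

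The largest falls included 4 neighbouring genes of lysosomal alpha-mannosidases on 2L. LManV (8772946 to 8776263) fell from 980 ± 118 to 11.1 ± 5.32 TPM and LManVI from 1244 ± 150 to 38.5 ± 14.6 TPM, while LManIII fell by 6.36 and LManIV fell by 4.91 on the log2 scale. The predicted lipase CG6295 fell from 2357 ± 308 to 30.9 ± 13.4 TPM, a log2 change of -6.30 ± 0.27 (limma adjusted p = 8.6e-08). The predicted lipases CG17192, CG31091 and CG31089 fell by 6.01, 5.94 and 5.82 on the log2 scale. ninaD, a scavenger receptor needed for carotenoid uptake, fell from 556 ± 74.3 to 10.5 ± 5.26 TPM, and CG14500 from 61.1 ± 13.5 to 0.674 ± 0.224 TPM.

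**Figure D1:**
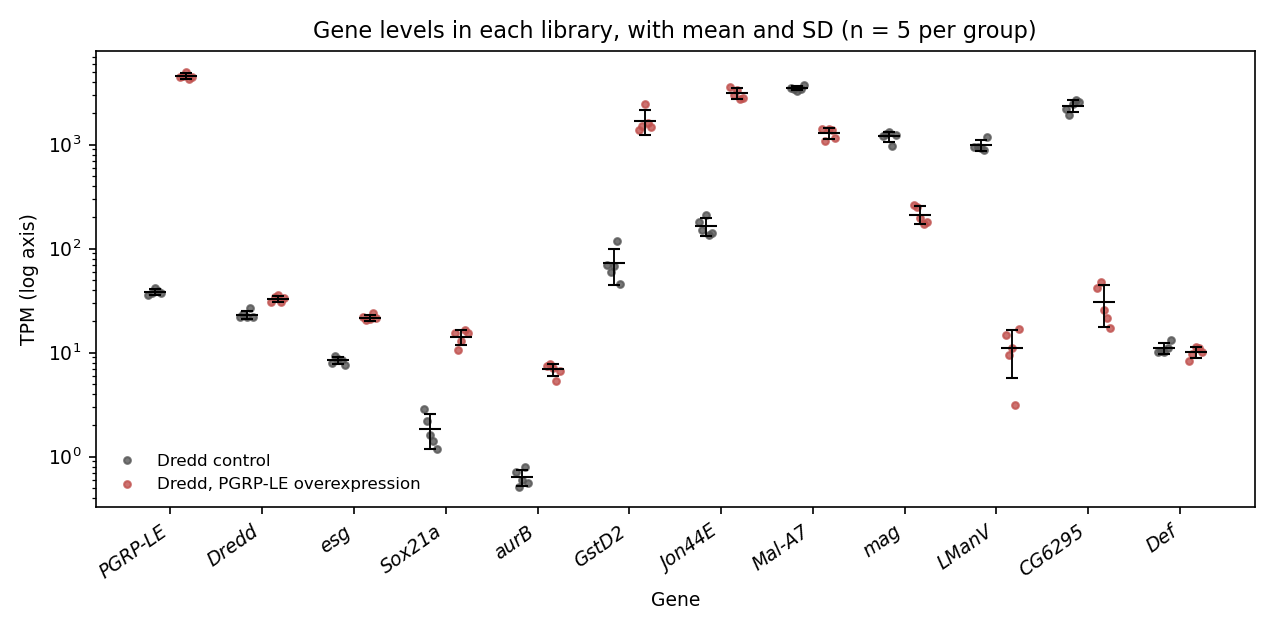
TPM on a log axis for 12 genes in each of the 5 control (grey) and 5 PGRP-LE overexpression (red) libraries, with mean (black line) and SD (bars). PGRP-LE averages 38.2 and 4534 TPM, LManV 980 and 11.1 TPM, and the groups of Def overlap at 10.99 and 10.1 TPM.

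Genes of intestinal stem cells and enteroblasts, the progenitor cells of the gut, and of the cell cycle rose together. Of 11 tested progenitor markers, 10 rose and 0 fell, both over all genes and adjusted over the list alone, with a median log2 change of 1.24. esg, a transcription factor of progenitors, went from 8.40 ± 0.653 to 21.7 ± 1.39 TPM, the progenitor factor Sox21a from 1.86 ± 0.686 to 14.2 ± 2.37 TPM, and the Notch target E(spl)m3-HLH from 2.77 ± 0.515 to 16.0 ± 2.27 TPM (SD, n = 5). Of 17 cell cycle and DNA replication genes, 16 rose, also adjusted over the list alone, with a median of 1.1 on the log2 scale. Among them the mitotic kinases aurB (0.633 ± 0.113 to 6.89 ± 0.938 TPM) and polo (0.372 ± 0.0784 to 2.87 ± 0.304 TPM) and RnrL, a subunit of ribonucleotide reductase (2.29 ± 0.507 to 9.92 ± 0.940 TPM), had the smallest p. Both kinases lay below 1 TPM in every control library and met the level for testing only through the overexpression libraries. The list had 22 matched genes, of which these 17 were tested. In limma's camera the progenitor list had an adjusted p = 4.13e-04 and the cell cycle list 2.78e-06. Both had an adjusted p = 0.458 with an estimated correlation. Of the 5 lists that passed camera, 0 passed with an estimated correlation. The size of these medians moved with the settings: the cell cycle median was 1.535 with a pseudocount of 0.1 and 0.46 with 5, with 16 genes rising in both. The progenitor median was 0.57 without the filter (13 of 15 rose) and 1.79 with a mean of at least 5 TPM (7 of 7 rose). Alongside, the medians of other cell types and regions ran from -0.60 for Malpighian tubules to 0.11 for haemocytes. They were 0.04 for enteroendocrine cells, 0.03 for neurons, -0.03 for visceral muscle, -0.14 for the copper cell and iron region, -0.155 for trachea, -0.19 for fat body and -0.36 for the proventriculus and salivary gland. Some of these medians rest on a small part of the list, because the other genes were below the level for testing. Tested were 3 of 15 haemocyte genes, 2 of 7 of the proventriculus and salivary gland, 6 of 12 of neurons and 7 of 15 of fat body. These medians therefore say little about those cells.

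Digestive enzymes of carbohydrates fell. Of 16 tested genes, 12 fell and 2 rose, counts that were the same adjusted over the list alone, with a median log2 change of -0.71. The maltase Mal-A7 fell from 3479 ± 169 to 1290 ± 151 TPM, the glucosidase tobi from 4307 ± 314 to 2040 ± 165 TPM and the amylase Amy-d from 3278 ± 357 to 1246 ± 178 TPM. The 2 that rose, Gba1a and Gba1b, encode glucocerebrosidases, which act on glycolipids rather than on food starch, and were named after their values were seen. camera gave an adjusted p = 4.13e-04 for the list, and an adjusted p = 0.677 with an estimated correlation. Summed over the list, TPM was 39650 ± 1891 in controls and 24090 ± 2070 with overexpression (exact permutation test, p = 0.00794, adjusted 0.0152).

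Of 27 lipid metabolism genes, 15 fell and 4 rose, also adjusted over the list alone (median -0.29, camera adjusted p = 0.0103, and adjusted p = 0.598 with an estimated correlation). The lipase mag fell from 1198 ± 133 to 212 ± 41.4 TPM. Npc2a rose from 62.7 ± 10.3 to 424 ± 40.4 TPM and Npc2e from 116 ± 24.5 to 943 ± 76.7 TPM, and both encode sterol-binding proteins.

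Digestive serine proteases moved in both directions, with 15 rising and 12 falling of 30, or 13 and 13 under median-of-ratios rescaling. Jon44E rose from 164 ± 31.2 to 3107 ± 362 TPM and epsilonTry from 643 ± 73.3 to 2429 ± 363 TPM, whereas thetaTry fell from 739 ± 86.4 to 128 ± 14.6 TPM. The summed TPM of the list was 103600 ± 7394 in controls and 81400 ± 6697 with overexpression (SD, n = 5; exact permutation test, p = 0.00794, adjusted 0.0152).

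Genes of detoxification also split. Of 70 cytochrome P450 genes, 37 fell and 16 rose, or 37 and 17 adjusted over the list alone (median -0.21, camera adjusted p = 4.13e-04, and adjusted p = 0.458 with an estimated correlation). Their summed TPM was 7022 ± 195 in controls and 7162 ± 406.5 with overexpression (exact permutation test, p = 0.611). Cyp4d8 fell from 29.2 ± 3.02 to 5.99 ± 0.581 TPM and Cyp12c1 rose from 91.8 ± 3.96 to 502 ± 79.3 TPM. Cyp12d1-d rose from 0.0956 ± 0.0438 to 17.5 ± 1.88 TPM and its near-identical copy Cyp12d1-p fell from 124 ± 3.52 to 51.4 ± 3.63 TPM, so the level of each is uncertain. Of 33 glutathione S-transferases, 16 rose and 10 fell, or 16 and 11 adjusted over the list alone, and the list did not pass camera (adjusted p = 0.789). Summed over that list, TPM was 8030 ± 54.0 in controls and 13210 ± 1536 with overexpression (exact permutation test, p = 0.00794, adjusted 0.0152). GstD2 rose from 72.0 ± 27.0 to 1683 ± 450 TPM and GstD5 from 103 ± 12.8 to 1608 ± 234 TPM. GstE1 fell from 297 ± 6.39 to 76.0 ± 7.52 TPM and GstT4 from 1055 ± 77.9 to 362 ± 22.8 TPM. Of 29 UDP-glycosyltransferases, 9 rose and 12 fell (camera adjusted p = 0.162), among them Ugt36A1 and Ugt301D1, which rose, and Ugt37B1, which fell from 64.8 ± 10.1 to 6.89 ± 1.53 TPM. The sum of that list was 1279 ± 69.2 and 1281 ± 78.6 TPM in controls and with overexpression (exact permutation test, p = 0.976).

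**Figure D2:**
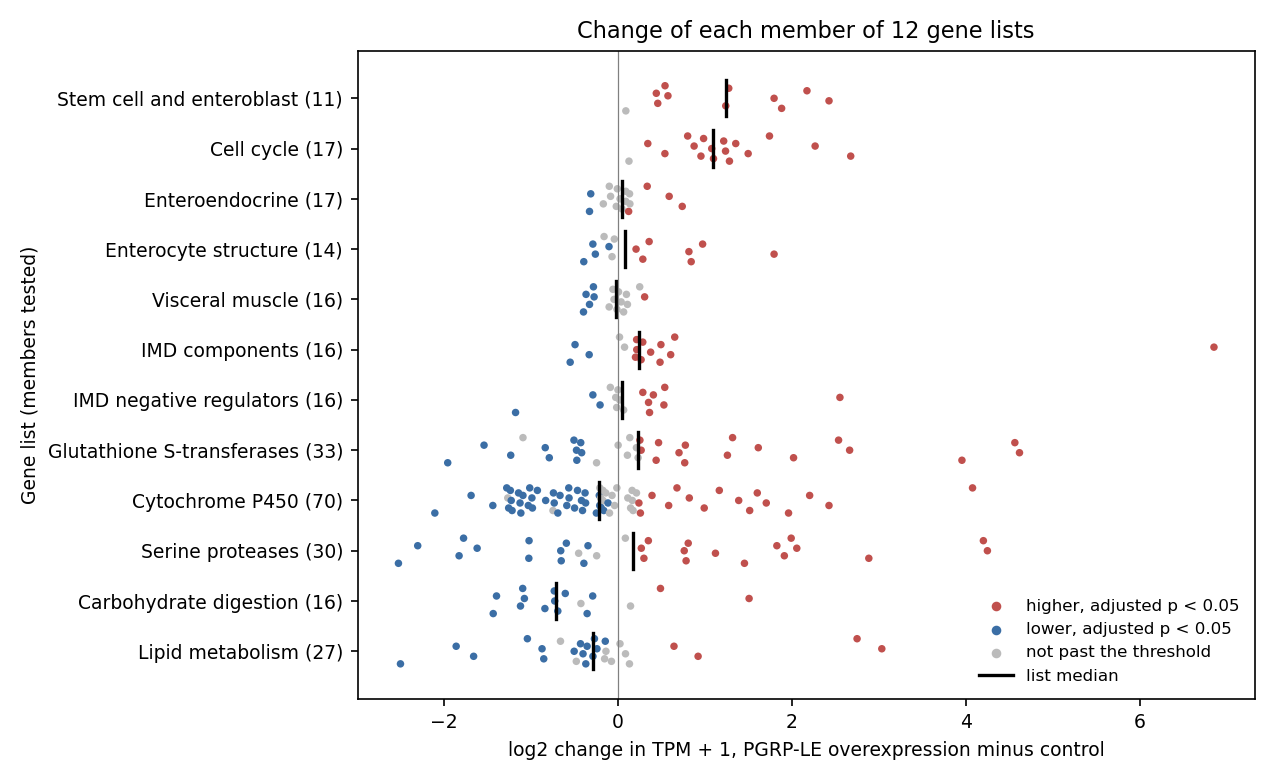
Log2 change in TPM + 1 (overexpression minus control) of each tested member of 12 gene lists, with the number tested in brackets. Points are red or blue where the gene was higher or lower past the threshold and grey otherwise, and black lines are list medians, which reach 1.24 for the stem cell and enteroblast list and -0.71 for carbohydrate digestion.

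Antimicrobial peptide genes, the usual targets of the IMD pathway, were at low levels in both groups. Of 14 listed, 1 met the level for testing. Def, which encodes defensin, stood at 10.99 ± 1.29 TPM in controls and 10.1 ± 1.16 TPM with overexpression (SD, n = 5; limma adjusted p = 0.273). Outside the test, DptA lay between 0.089 and 0.649 TPM in controls and between 0.293 and 0.786 TPM with overexpression, and CecA1 reached 12.8 TPM in 1 control library while all overexpression libraries were listed at 0.

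Of 16 IMD pathway components, 11 rose, PGRP-LE among them, and 3 fell, or 7 and 4 under median-of-ratios rescaling (camera adjusted p = 0.214). The ubiquitin-conjugating enzymes ben and eff rose from 85.5 ± 1.91 to 135 ± 4.74 TPM and from 217 ± 6.75 to 330 ± 6.04 TPM. PGRP-LC, the membrane receptor of the pathway, fell from 44.5 ± 1.297 to 30.1 ± 2.34 TPM. Of 16 negative regulators, 7 rose and 3 fell, or 6 and 5 under median-of-ratios rescaling, where the sign of the list's median turned from 0.04 to -0.04 (camera adjusted p = 0.767). PGRP-SC1a, an amidase that degrades peptidoglycan, rose from 7.73 ± 1.90 to 50.02 ± 10.7 TPM, with the caution that PGRP-SC1b is a near-identical copy. casp and RYBP rose by 0.35 and 0.41 on the log2 scale, and dnr1 fell from 38.2 ± 11.3 to 15.9 ± 1.505 TPM.

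Of 19 Drosomycin-family and Toll-type effectors, 4 fell and 1 rose, or 2 and 0 adjusted over the list alone (camera adjusted p = 0.322). Drsl4 fell from 2.15 ± 0.689 to 0.337 ± 0.116 TPM and Drsl5 from 2.47 ± 1.13 to 0.137 ± 0.145 TPM. BomS1 was called higher, at 10.9 ± 3.76 and 21.9 ± 10.4 TPM (limma adjusted p = 0.0435), a call that ended when any of 7 single libraries was left out (adjusted p from 0.0644 to 0.0942). The call also ended under median-of-ratios rescaling, quantile normalization, array weights, a replicate block and 1 factor of unwanted variation (limma adjusted p from 0.0524 to 0.106). Of 6 lysozymes, 3 fell and 2 rose (camera adjusted p = 0.482). LysB fell from 626 ± 168 to 75.0 ± 30.8 TPM and LysE from 29.7 ± 7.98 to 4.24 ± 1.26 TPM, while LysX rose from 16.3 ± 9.92 to 248 ± 77.1 TPM. LysB and LysE share near-identical sequence and their separate levels are uncertain. LysX lies on the opposite strand, and its likeness in sequence to the other copies was not measured. Over the tested lysozymes, summed TPM was 5938 ± 1373 in controls and 1254 ± 430 with overexpression (exact permutation test, p = 0.00794, adjusted 0.0152).

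Signalling and stress lists changed in part. Of 10 JAK/STAT genes, 5 rose and 1 fell (camera adjusted p = 0.879), while their summed TPM was 396 ± 59.6 in controls and 316.5 ± 34.55 with overexpression (exact permutation test, p = 0.0238, adjusted 0.0417). The phosphatase gene Ptp61F and the receptor gene dome rose by 0.44 and 0.27 on the log2 scale. vir-1 fell from 222 ± 20.8 to 124 ± 19.0 TPM, by more than the sum of the JAK/STAT list. Turandot genes, stress-induced secreted proteins, had 0 calls among 3 tested (camera adjusted p = 0.618). Of 14 JNK and apoptosis genes, 8 rose and 3 fell, or 5 and 3 under median-of-ratios rescaling (camera adjusted p = 0.599), with the kinase hep, the caspase Dronc and Gadd45 rising by 0.50, 0.65 and 0.71. In the EGFR list 4 of 9 rose and 0 fell (camera adjusted p = 0.486). Krn, an EGFR ligand, and Egfr rose by 0.58 and 0.31, and Pvf1, which is a ligand of another receptor, rose from 20.7 ± 3.44 to 79.4 ± 8.66 TPM. Of 16 insulin and TOR genes, 8 fell and 5 rose, or 9 and 5 adjusted over the list alone and 9 and 2 under median-of-ratios rescaling (camera adjusted p = 0.162), with falls of foxo from 47.3 ± 1.84 to 29.9 ± 2.86 TPM and of Thor from 1105 ± 116 to 690 ± 63.0 TPM, and of S6k by 0.38 on the log2 scale.

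Of 23 autophagy genes, 12 rose and 6 fell, or 8 and 8 under median-of-ratios rescaling (camera adjusted p = 0.925). Atg5 rose from 13.3 ± 0.597 to 22.3 ± 1.196 TPM, Atg8a from 555 ± 25.6 to 741 ± 34.7 TPM and the lysosomal membrane gene Lamp1 from 415 ± 19.6 to 518 ± 14.8 TPM, while Pi3K59F, a lipid kinase that acts in autophagosome formation, fell from 17.9 ± 1.01 to 12.8 ± 0.552 TPM. Of 18 redox enzymes, 9 fell and 7 rose, or 10 and 4 under median-of-ratios rescaling (camera adjusted p = 0.162). The peroxiredoxin Prx6c fell from 91.5 ± 16.4 to 15.5 ± 3.28 TPM, catalase (Cat) from 367 ± 19.2 to 248 ± 14.03 TPM and Sod1 from 944 ± 32.8 to 706 ± 17.2 TPM. Of 15 heat shock genes, 4 rose and 2 fell (camera adjusted p = 0.877). Hsp70Aa and Hsp70Bb rose by 2.87 and 2.08 on the log2 scale, with uncertain levels because the Hsp70 copies are near-identical, and stv fell by 0.45. Of 15 unfolded protein response genes, 4 rose and 3 fell, or 4 and 5 under median-of-ratios rescaling (camera adjusted p = 0.925). ERp60 and Calr, chaperones of the endoplasmic reticulum, rose by 0.82 and 0.50, and Herp fell by 0.47.

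Markers of gut cell types and regions other than the progenitors moved in both directions. Of 14 enterocyte structure genes, 7 rose and 4 fell, whereas median-of-ratios rescaling gave 5 and 7 (camera adjusted p = 0.925). The septate junction genes Tsp2A and Ssk rose from 325 ± 31.0 to 636 ± 38.5 TPM and from 637 ± 57.9 to 1140 ± 79.8 TPM, and the transcription factor Sox100B, which is also in the progenitor list, from 4.04 ± 1.28 to 16.0 ± 1.503 TPM. Of 17 enteroendocrine genes, 4 rose and 2 fell, with 3 and 2 adjusted over the list alone and 3 and 3 under median-of-ratios rescaling (camera adjusted p = 0.925). The peptide genes CCHa1, CCAP and NPF rose by 0.59, 0.74 and 0.33. Of 15 copper cell and iron region markers, 5 fell and 2 rose (camera adjusted p = 0.111). The metallothioneins MtnC and MtnA fell from 5846 ± 948 to 1718 ± 372 TPM and from 18489 ± 4900 to 6106 ± 1729 TPM, and lab, a transcription factor of copper cells, fell by 0.52. Of 12 peritrophic matrix and mucin genes, 5 rose and 2 fell (camera adjusted p = 0.599), with Peritrophin-15b at 38.0 ± 5.99 and 271 ± 25.5 TPM, Peritrophin-15a at 538 ± 51.5 and 1377 ± 158 TPM, and Crys rising by 1.26.

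Among 14 amino acid transporters 4 fell and 2 rose (camera adjusted p = 0.322), with the glutamate transporter Eaat1 falling from 56.7 ± 7.92 to 17.4 ± 2.60 TPM, sbm falling by 0.56 and CG8785 rising by 0.59. Of 8 ecdysone response genes, 5 fell and 3 rose (camera adjusted p = 0.322), whereas without the filter on low values 5 fell and 6 rose of 14 and the median turned from -0.21 to 0.01. Their summed TPM was 329.7 ± 65.2 in controls and 480.1 ± 29.5 with overexpression (SD, n = 5; exact permutation test, p = 0.00794, adjusted 0.0152). Eip75B and Hr39, both nuclear receptors, fell by 0.55 and 0.35, while Ldh, which encodes lactate dehydrogenase, rose from 130 ± 14.3 to 222 ± 20.0 TPM. Of 9 circadian clock genes, 2 fell and 1 rose, or 2 and 3 with array weights and 3 and 3 without control replicate 4 (camera adjusted p = 0.482), with cry at 133 ± 9.44 and 67.8 ± 5.38 TPM, Clk falling by 0.78, and tim at 62.1 ± 46.9 and 163 ± 20.6 TPM, a control mean that includes 1 library at 145 TPM. Of 85 cytosolic ribosomal protein genes, 19 rose and 11 fell, or 18 and 10 adjusted over the list alone, but 8 and 36 under median-of-ratios rescaling. That rescaling turned the list's camera result from an adjusted p of 0.636 to 0.0201, downward, with the preset correlation. The estimated correlation of this list was 0.651, with a camera adjusted p of 0.963 in the TPM as deposited. RpS5b rose from 0.332 ± 0.113 to 4.88 ± 0.782 TPM, and RpLP2 and RpS15Ab rose by 0.44 and 0.47.

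Markers of other tissues moved in part. Of 16 visceral muscle genes, 5 fell and 1 rose (camera adjusted p = 0.322), with Mlp84B and bt falling by 0.40 and 0.33 and Zasp52 rising by 0.30. Of 6 neuronal genes, 2 rose and 2 fell, or 1 and 2 under median-of-ratios rescaling (camera adjusted p = 0.651); nSyb fell by 0.58, Vmat by 0.29, and Syx1A rose by 0.30. Of 7 tracheal genes, 3 fell and 1 rose (camera adjusted p = 0.322), with uif and Gasp falling by 0.59 and 0.43 and tyn rising by 0.69. Of 12 Malpighian tubule genes, 3 fell and 1 rose, or 5 and 1 under median-of-ratios rescaling (camera adjusted p = 0.0933). ry fell from 17.5 ± 2.64 to 7.83 ± 0.4999 TPM, Drip fell by 0.28, a call that array weights ended (adjusted p = 0.0993), and Prip rose by 0.54. In the haemocyte list 1 of 3 rose, or 0 under median-of-ratios rescaling, and 1 fell, crq, from 98.3 ± 5.43 to 66.6 ± 1.47 TPM (camera adjusted p = 0.709). Both tested proventriculus and salivary gland genes fell, dve by 0.37. Of 7 fat body genes 1 rose, Lsp1gamma (1.07 ± 0.533 and 2.46 ± 1.06 TPM, limma adjusted p = 0.0226), or 0 adjusted over the list alone and 1 with 2 falling under median-of-ratios rescaling, and the call ended without control replicate 1, control replicate 2 or overexpression replicate 1 (adjusted p from 0.0514 to 0.0555; list camera adjusted p = 0.429). Of 24 male reproductive tract genes listed, 23 were matched to the table, and 0 of these reached the level for testing. The median change in the TPM as deposited was above 0 for the heat shock, unfolded protein response, serine protease and enteroendocrine lists. It was also above 0 for the clock, neuronal, haemocyte and ribosomal protein lists. For all of these camera gave a downward direction. It compares test statistics, scaled by each gene's variability, with those of the other genes, so its direction need not match that of the log2 changes. The lysozyme and ecdysone lists had a negative median and a positive mean. Over the 37 lists with a tested member, 30 had the same counts adjusted over the list alone.

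A total of 8681 genes of the authors' deposited table could be set beside the fit described here, and the log2 changes had a Pearson r of 0.959 and a Spearman rho of 0.991 across genes, which are not independent replicates. The sign was the same for 8466. After Benjamini-Hochberg adjustment of the p-values in the authors' deposited table, 4557 of these genes passed, against 5470 here, and 4446 passed in both, all 4446 with the same sign. The authors' deposited table gives a log2 change of 6.843 for PGRP-LE and 0.49 for Dredd.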

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

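The tests of progenitor genes, of summed copies, of large changes by chromosome, of X as a reference and of the second chromosome as a whole cause were chosen after the results were seen, while the splits and the odds ratios of calls on the second chromosome and the third against all other arms were set beforehand. Each group of 5 was examined for a library far from the others, over the named genes and 5 library measures. Of 258 such groups, 20 had one, and chance alone gives about 1 in 20, or 12.9.

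Control replicate 5 was apart in several neighbouring mannosidase genes, with LManV at 1186 TPM against 884 to 950 in the other controls, LManIII at 347 TPM and LManIV at 45.8 TPM, and its polo level was 0.235 TPM. Control replicate 4 had tim at 145 TPM, where the other controls lay between 33.9 and 55.4, and mag at 968 TPM. Control replicate 3 had eff at 229 TPM, Clk at 14.04 TPM and Vmat at 10.98 TPM. Control replicate 2 had dnr1 at 57.4 TPM against 29.5 to 37.1, Syx1A at 22.7 TPM and uif at 3.83 TPM, and control replicate 1 had Ugt301D1 at 14.5 TPM. Overexpression replicate 3 had GstD2 at 2471 TPM against 1365 to 1618, thetaTry at 102 TPM and Ldh at 257 TPM. Overexpression replicate 4 had CG31091 at 1.604 TPM, Drip at 41.3 TPM and Cyp12d1-d at 14.2 TPM, and overexpression replicate 5 had Eaat1 at 22.0 TPM. Transcript rows that matched no annotated gene, used in no comparison, held 0.042% of TPM with overexpression and 0.0354% in controls, with every overexpression library above every control library (exact permutation test, p = 0.00794, adjusted 0.0152).

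Both counts of changed genes were set against regroupings of the libraries. The true genotypes gave 3499 higher and 1991 lower genes, and 1 of 100 splits, the true one, gave as many in either direction. The highest count in any other split was 1 gene. Every other split mixes the genotypes, which raises the variance within its groups, so low counts there follow from the design. As 1 of 100 is also the smallest share possible here, these splits cannot exclude chance.

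Called genes were somewhat more frequent on the second chromosome, at 65.1% of genes on 2L and 2R against 61.6% elsewhere (odds ratio 1.16, 95% interval 1.06 to 1.27; Fisher's exact test across genes, which are not independent, p = 0.00109), and for changes of at least 1 on the log2 scale the odds ratio was 1.16 with an interval of 0.981 to 1.36. Background differences brought by the UAS-PGRP-LE chromosome may contribute, although local effects of that chromosome as the whole cause are argued against by the 61.6% of genes called on X, 3L and 3R. The third chromosome had an odds ratio of 0.947 (95% interval 0.868 to 1.03) against a reference that held the second. Against X alone, which had the fewest calls (59.8%), the odds ratios for calls and for changes of at least 1 were 1.25 (1.104 to 1.425) and 1.55 (1.19 to 2.02) for the second chromosome and 1.11 (0.979 to 1.26) and 1.47 (1.13 to 1.91) for the third, so the background of both stays open. A response to PGRP-LE itself stays open too, as no group carried the UAS chromosome without the driver.

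The rise of stem cell, enteroblast and cell cycle genes could in principle follow from a lower share of enterocyte RNA, which would raise the markers of every other cell type alike. The median log2 change of the enteroendocrine list lay below that of the progenitor list, a difference of -1.19 (permutation test across genes, which are not independent, p = 8e-05). This comparison was chosen after both medians were seen, and the progenitor median moved with the filter. For these lists, the difference argues against a lower enterocyte share as the whole cause. After median-of-ratios rescaling the progenitor median was 1.14, with 10 of 11 genes past the threshold, so these genes rose relative to the median gene. The factors of that rescaling ran only from 0.932 in control replicate 5 to 1.07 in overexpression replicate 3. They could not have removed a rise of this size, so this is no test of the scaling of each library to one total. More progenitors, more expression per progenitor cell, and an effect of genetic background stay open, and none of these was tested.

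Near-identical copies that moved in opposite directions may reflect reads of the same transcripts assigned to another copy, for example through strain variants. The sum of LysB, LysC, LysD, LysE and LysX fell by 2.34 ± 0.31 on the log2 scale (SE), from 5905 to 1203 TPM. This argues against reassignment among these copies as the whole cause of the falls. The sum cannot decide whether the rise of LysX, from 16.3 to 248 TPM, came from reassigned reads, as that rise is small beside it. The likeness of LysX to the other copies was not measured. For the 6 Hsp70 copies, whose single changes spanned 4.81, the sum changed by 0.51 ± 0.36 (SE), and reassigned reads cannot be told apart from true changes of single copies because the sum varied widely between libraries. The summed level of Cyp12d1-d and Cyp12d1-p was 124 ± 3.51 TPM in controls and 68.9 ± 4.14 TPM with overexpression.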

How the results depend on the processing

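In the settings tried, 0 named genes reversed direction, and the 5 lists that passed camera kept theirs. Of the other lists, the median changed sign in 12 and the camera direction in 6 under some setting, none of these 6 past the threshold for camera. A minimum log2 change of 1 left 336 genes higher and 297 lower, fewer by construction. With an estimated correlation 0 of the 5 gene lists passed camera. The estimates were 0.347 for carbohydrate digestion, 0.284 for the cell cycle, 0.209 for progenitors, 0.089 for lipid metabolism and 0.039 for cytochrome P450 genes. All lay above the preset 0.01, and a higher correlation makes camera stricter. Leaving out 1 library gave 3257 to 3556 genes higher, 1834 to 2044 lower, 5 lists each time, and log2 changes of 6.81 to 6.88 for PGRP-LE and 0.46 to 0.54 for Dredd. Replicate numbers 1, 3, 4 and 5 did not pair the libraries (correlations of same-numbered deviations from -0.233 to 0.065), but both replicates 2 deviated together (0.57), each the closest to the other, at 20.6 and 20.9 on the second principal component, where the other libraries reached at most 7.31. A replicate block gave 3173 higher and 1803 lower. Among alternatives added after seeing the data, spike-in rescaling gave 2582 and 1649, and omitting replicate 2 of both groups 3131 and 1789. Of the named genes' alternative values, 3017 kept direction and side of the threshold and 23 lost the call, 14 for BomS1, 7 for Lsp1gamma and 2 for Drip. The correlation with the authors' deposited table was 0.959 with 1 factor of unwanted variation too. TPM keeps no depth, so what depth limits is unknown.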

Other observations

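The gene families, neighbouring genes and transcription factor targets below, and all tests on them, were chosen after the data were seen. Of 56 families with at least 8 tested members, 18 passed limma's camera and 0 with an estimated correlation. Families were defined by a shared symbol prefix, with exceptions. The proteasome family was put together from Pros, Rpn and Rpt symbols, Rpt4R among them, and the mitochondrial genome's genes were taken by chromosome. Proteasome subunits rose without exception among those tested, 34 of 34, with a median log2 change of 0.71 (camera adjusted p = 2.15e-13, and adjusted p = 0.465 with an estimated correlation) and 0.61 under median-of-ratios rescaling. Rpn10, for example, went from 76.2 ± 2.69 to 131 ± 6.30 TPM (SD, n = 5). Proteins of the mitochondrial ribosome rose too, 46 of 47 for the large subunit (mRpL, median 0.47) and 25 of 26 for the small one (mRpS, median 0.41), as did 8 of 8 subunits of the CCT chaperonin, 10 of 10 of the EMC membrane insertion complex and 20 of 21 nucleoporins. Under median-of-ratios rescaling 43 mRpL and 23 mRpS genes rose and 1 of each fell, and 8 CCT, 8 EMC and 18 nucleoporin genes rose. Of 33 genes with the ND prefix of respiratory complex I, 26 rose and 0 fell (median 0.21), but 16 rose and 2 fell under median-of-ratios rescaling (median 0.11), while of 13 genes encoded by the mitochondrial genome 7 fell and 0 rose, or 7 and 2 under quantile normalization. Among serpins 9 of 13 fell and 0 rose, and of 13 GstE genes 8 fell and 2 rose, whereas of 11 GstD genes 9 rose and 0 fell.

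Around 3 of the largest rises, 7 of the 14 other tested genes within 10 kb rose, 1 fell and 6 did not pass, against 40.1% of all tested genes that rose, and the difference was not tested. Next to CG5883 on 3L, Rpt4R went from 0.0196 ± 0.0111 to 6.11 ± 0.217 TPM and CG7252 from 0.496 ± 0.296 to 2.33 ± 0.357 TPM, while byn fell by 0.40 on the log2 scale. Beside Mov10 on 2R, CG8950 (17059331 to 17062634) went from 3.41 ± 0.902 to 43.0 ± 7.28 TPM, and CG30460, which overlaps Mov10, stood at 9.38 ± 0.577 and 8.57 ± 0.632 TPM. Around CG33468 on 2R, CG33469 went from 6.49 ± 0.473 to 29.6 ± 1.17 TPM and CG12868 from 94.6 ± 7.53 to 735 ± 159 TPM, while tra2 in the same interval stood at 13.4 ± 0.842 and 13.6 ± 1.09 TPM.

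The joint rise of GstD and proteasome genes raised the hypothesis of activity of the CncC transcription factor, which is reported to drive both. GstD2, GstD4 and GstD5 lie close together on 3R (12371971 to 12376572), so their rises need not be independent. Of 12 other reported targets, 5 rose and 5 fell, or 5 and 6 under median-of-ratios rescaling. The share that rose was 41.7% (exact binomial 95% interval 15.2 to 72.3), against 40.1% of the other tested genes (odds ratio 1.07, 95% interval 0.338 to 3.36). Cyp6a8 rose from 18.7 ± 4.26 to 62.5 ± 8.30 TPM, and Prx2, Ho, ref(2)P and Trxr1 rose by 0.50, 0.39, 0.35 and 0.34 on the log2 scale. Gclc, a glutathione synthesis gene, fell from 194 ± 29.9 to 107 ± 16.5 TPM and Cyp6a2 from 86.9 ± 26.5 to 35.9 ± 10.7 TPM, and Zw, Pgd and Gclm also fell. With so few targets moving both ways, CncC activity stays open.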
